A study of Mus musculus with 12 samples.

How the data were processed

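Gene-level read counts deposited by the authors were used as given, for 35976 gene symbols and 12 libraries. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2, counted with featureCounts and tested with DESeq2. Versions of these tools, the annotation release, strand use and the handling of reads with several matches are not given in the sources used here. Per the labels, RNA was purified on RNeasy columns and sequenced as stranded polyadenylated TruSeq libraries. Gene positions came from the RefSeq annotation of GRCm38.p6 and were found for 33458 genes (93%). No count was seen in any library for 10859 genes. Library totals ran from 18292636 to 25732049 counts.

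Genes were filtered with filterByExpr, which kept 15334, and scaled with TMM factors of 0.928 to 1.051. One quasi-likelihood model with robust dispersion was fitted to all 12 libraries in edgeR, with a biological coefficient of variation of 5.87%, 18.61 prior and 8 residual degrees of freedom. The 7 comparisons were BN1, MA9 and ME each against WT, the leukemias against each other, and BN1 against the mean of MA9 and ME. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Median absolute log2 fold changes were 0.71, 0.75, 0.72, 0.48, 0.44, 0.23 and 0.45 in that order, BN1 against MA9 being the fourth. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

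The 28 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Their subjects were HoxA, HoxB, other MLL fusion targets, mouse counterparts of human 10p12 genes, fusion partners and cofactors, stem cells, early progenitors, primary granules, neutrophils, monocytes, dendritic cells, MHC class II, early and mature B cells, T cells, NK cells, erythroid cells, megakaryocytes, eosinophils with basophils and mast cells, stroma, cell cycle, Myc and ribosome biogenesis, glycolysis, interferon response, p53 targets, the Bcl2 family, immediate early genes and mitochondrially encoded genes. Ighm, Ighd, Trac, Trbc1, Trbc2 and Ahsp were absent from the table, and 16 members were matched by another symbol. Camera was repeated with an estimated correlation, and fry from limma was run as another test.

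Genes were named by rule. These were the 8 largest changes per direction and comparison among called genes without overlap of the groups and with at least 5 CPM in the higher group, leaving out symbols of the Gm, Rik and -ps kinds and immunoglobulin and T cell receptor segments. The rule went by symbol alone, so Rps4l, annotated as a transcribed pseudogene, and LOC108168967, without an annotated location, were kept. Groups of 3 against 3 show no overlap by chance in 10% of cases. Some genes that the rule selects are not reported here. Added were up to 4 called members per direction of each list, and Nutm1, Brd9, Kmt2a, Mllt1, Mllt3, Hoxa9, Meis1, Myc, Kit, Cd34, Bmi1 and Ptprc. Zinc finger genes of chromosome 2, the Y-linked genes with Xist, and LOC101056014 with Lars2 were named after their values were seen. Ptprc, the gene of CD45, stood at 997 ± 78.7 CPM in WT, 498 ± 21.0 in BN1, 382 ± 29.2 in MA9 and 324 ± 9.11 in ME.

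Alternatives were DESeq2, limma-voom, other scaling, other filters, each library left out, a block for the replicate number and a 2-fold minimum. Fits without structural RNA-like genes and without X and Y genes were added after seeing the data. With 200 genes changed in simulated data, recovery at 2-fold was 89.4% to 98.5% over the comparisons. At 1.5-fold it was 68.7% to 86.6%, at 1.25-fold 43.3% to 67.2%, and false calls made up 4.3% to 6.3%. Real comparisons called 40.6% to 80.1% of genes, so these rates may not carry over. Sharing of WT libraries was examined in 20 simulations of unchanged groups. No replicate pair was a duplicate (mean chi-square at least 2.005).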

Results

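Gene expression was measured by sequencing polyadenylated RNA from CD45.2-positive cells sorted from mouse bone marrow. The 12 libraries formed 4 groups of 3, namely normal marrow (WT) and leukemias carrying BRD9-NUTM1 (BN1), MLL-AF9 (MA9) or MLL-ENL (ME). CD45.2 is an allelic form of the leukocyte surface protein encoded by Ptprc and is commonly used to tell donor from host cells. MLL fusions join the amino-terminal part of the histone methyltransferase MLL (Kmt2a in the mouse) to partners such as AF9 (Mllt3) or ENL (Mllt1). BRD9-NUTM1 joins BRD9, a bromodomain protein of a chromatin remodelling complex, to NUTM1, a protein of the male germ line. Library totals were 19170183 to 21432949 counts in WT, 21942608 to 25732049 in BN1, 18953495 to 22112345 in MA9 and 18292636 to 21693465 in ME. No label says that the 3 libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

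Levels are CPM, counts scaled to library size, as mean ± SD (n = 3 libraries per group). Log2 fold changes are edgeR estimates ± approximate SE, with Benjamini-Hochberg adjusted p. This SE understates counting error where a group has few counts (Dmrtb1 has 5 in WT). Folds against a group without counts are lower bounds from a floor of 3 counts over the group. Ratios against 1 to 3 counts carry an interval, and bounds and intervals cover counting error only. Gene positions refer to the mm10 (GRCm38) assembly and to protein-coding genes. The library kit keeps the strand, but whether counting used it is not given in the sources used here, so levels of overlapping or closely similar genes such as Hoxb5os and Hoxb5, Hba-a1 and Hba-a2, or Rps4l are uncertain. Correlations of log CPM across genes were 0.991 to 0.994 within groups and 0.79 to 0.80 between WT and leukemia libraries. BN1 and MA9 libraries correlated at 0.911 to 0.913, BN1 and ME at 0.921 to 0.924, and MA9 and ME at 0.954 to 0.956. Structural RNA-like genes took 1.85% of the counts in ME replicate 3 and from 0.0475% to 0.0764% in every other library. LOC101056014 stood at 14795 CPM in that library and at 455 and 446 CPM in the other ME libraries, and Lars2 at 3508 against 136 and 140 CPM.

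The fusion partner genes were examined first as a check of the labels. Mouse Nutm1 (chromosome 2, from 112247948 to 112259291) gave 0.158 ± 0.137 CPM in WT, 0.882 ± 0.164 in BN1, 6.27 ± 0.402 in MA9 and 0.975 ± 0.555 in ME, and was higher than in WT by 2.41 ± 0.54 (log2) in BN1, 5.24 ± 0.40 in MA9 and 2.52 ± 0.54 in ME. Brd9 (chromosome 13, from 73937801 to 73960895) stood at 90.3 ± 3.80 CPM in WT, 74.1 ± 1.38 in BN1, 83.1 ± 2.74 in MA9 and 74.0 ± 3.05 in ME. Kmt2a was lower than in WT (159.5 ± 1.61 CPM) in BN1, MA9 and ME, at 138 ± 8.94, 113 ± 4.10 and 112 ± 15.1 CPM. Mllt3 fell from 20.8 ± 1.43 CPM in WT to 1.06 ± 0.366 in BN1, 1.68 ± 0.472 in MA9 and 2.67 ± 0.0759 in ME, while Mllt1 was higher in MA9 (0.64 ± 0.06) and ME (0.54 ± 0.06) and stood at 53.7 ± 3.59 CPM in BN1 against 51.3 ± 1.65 in WT. The labels do not state whether the constructs carry human or mouse sequence, so these values neither establish nor exclude a fusion in any library.

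BRD9-NUTM1 leukemia cells were first compared with normal marrow, which asks what separates this leukemia from the marrow it replaces. Genes of the HoxB cluster, homeobox transcription factors, rose in BN1, with Hoxb5 (chromosome 11, from 96303512 to 96306121) at 62.5 ± 3.99 CPM and Hoxb4 at 80.9 ± 6.53 CPM against 15.5 ± 1.47 in WT. Hoxa9 (chromosome 6, from 52223097 to 52227370), a homeobox factor central to MLL-rearranged leukemia, fell from 3.71 ± 0.178 CPM to 1 count over the 3 BN1 libraries, and its cofactor Meis1 fell to 0.126 ± 0.115 from 7.13 ± 0.925 CPM (-5.78 ± 0.29). Among genes of primary granules, the first granules made in myeloid differentiation, neutrophil elastase (Elane) rose to 5190.4 ± 170 against 221 ± 6.52 CPM and myeloperoxidase (Mpo) to 12054 ± 153 against 964 ± 34.5 CPM. Genes of mature neutrophils, red cells, B cells, T cells and NK cells fell. WT was a mixture of marrow lineages, in which haemoglobin genes took 2.92% to 3.80% of the counts against at most 0.0033% in any leukemia library.

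Of 15334 genes tested, 12146 were called in BN1 against WT, 5886 higher and 6260 lower (6171 and 6056 with upper-quartile scaling), and 5786 of them changed by at least 2-fold (2093 higher and 3693 lower). Largest among the rises were Slitrk2, a neuronal membrane protein, at 65.8 ± 1.01 CPM (at least 1230-fold higher), and Tdrd9, a helicase of the germ-line piRNA pathway (at least 1110-fold higher). The lipid receptor Gpr119 (at least 529-fold higher) and Dmrtb1, a transcription factor of male germ cells (11.87 ± 0.12), followed. Marco, a scavenger receptor of macrophages (chromosome 1, from 120474538 to 120505024), reached 79.8 ± 9.10 CPM (2230-fold higher, counting interval 617 to 18400). Also in this set were the HoxB antisense transcript Hoxb5os (at least 270-fold higher), the collagen gene Col6a4 (2520-fold higher, counting interval 452 to 99500) and Prickle2 (at least 172-fold higher). At the opposite end, with no counts in BN1, were Trim10 (at least 3540-fold lower), Tal1, a transcription factor of stem and red cells (at least 2600-fold lower), carbonic anhydrase 1 (Car1, at least 2510-fold lower) and Add2, a protein of the red cell skeleton (at least 2450-fold lower). Also without counts were Tspan33 (at least 3000-fold lower), Btnl10 (at least 2830-fold lower), Tspan13 (at least 2140-fold lower) and Slfn14 (at least 1410-fold lower). Adjusted p of these 16 genes ran from 1.6e-32 to 1.3e-13 in edgeR.

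By fixed lists, the HoxB cluster rose in BN1, with 6 of 7 members higher and none lower (6 adjusted over the list alone). The HoxB median log2 fold change was 7.46, with a camera adjusted p = 7.6e-06. The HoxA cluster went both ways, with 2 of 10 members higher and 6 lower (9 adjusted over the list alone). The HoxA median log2 fold change was -4.38 (-2.48 with genes at their bound), with a camera adjusted p = 0.35. Hoxa9 (270-fold lower, counting interval 47.9 to 10700) and Hoxa7 (221-fold lower, counting interval 39.1 to 8760) fell to 1 count each over the group. Non-Hox targets of MLL fusions were split, with 10 of 19 members higher and 8 lower (18 adjusted over the list alone). The MLL target median log2 fold change was 0.45, with a camera adjusted p = 0.14. Within them the RNA-binding protein Igf2bp3 rose (5.33 ± 0.11), whereas the receptor tyrosine kinase Flt3 fell (-9.04 ± 0.18) and Eya1 had no counts (at least 113-fold lower). Stem cell genes fell, with 2 of 14 members higher and 11 lower (13 adjusted over the list alone). The stem cell median log2 fold change was -4.48, with a camera adjusted p = 0.024 (adjusted p = 0.068 with an estimated correlation). Gata2 fell (-7.99 ± 0.20) and Cdkn1c rose (4.59 ± 0.14). Early progenitor genes showed 7 of 17 members higher and 10 lower (17 adjusted over the list alone). The early progenitor median log2 fold change was -3.02, with a camera adjusted p = 0.12. Among these, Cd93 (1.96 ± 0.04), Kit (1.28 ± 0.06), Myb (1.23 ± 0.04) and Myc (0.58 ± 0.06) rose, and Cd34 fell from 28.5 ± 1.73 to 0.602 ± 0.220 CPM. The mouse counterparts of human 10p12 genes reported high in NUTM1-rearranged B-cell leukemia had 4 of 7 members higher and 1 lower (5 adjusted over the list alone), with Bmi1, a Polycomb protein, rising by 0.83 ± 0.07 to 44.7 ± 3.86 CPM. The 10p12 counterpart median log2 fold change was 0.12, with a camera adjusted p = 0.48. Fusion partners and chromatin cofactors had 4 of 23 members higher and 16 lower (20 adjusted over the list alone), with Brd3 (-1.05 ± 0.05) and Psip1 (-1.24 ± 0.08) lower. The cofactor median log2 fold change was -0.27, with a camera adjusted p = 0.085.

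Of the myeloid lists, primary granule genes in BN1 had 10 of 14 members higher and 4 lower (14 adjusted over the list alone), including cathepsin G (Ctsg, 4.35 ± 0.05) and Ms4a3 (3.69 ± 0.09). The primary granule median log2 fold change was 1.83, with a camera adjusted p = 3.4e-05 (adjusted p = 0.071 with an estimated correlation). Mature neutrophil genes had 1 of 20 members higher and 19 lower (20 adjusted over the list alone). The neutrophil median log2 fold change was -3.44, with a camera adjusted p = 5e-15. The gelatinase Mmp9 fell (-4.92 ± 0.06), as did Retnlg (-4.39 ± 0.08) and Ly6g (-5.25 ± 0.09), while Chil3 rose (2.26 ± 0.05) to 18764 ± 877 CPM. Monocyte and macrophage genes had 10 of 23 members higher and 12 lower (22 adjusted over the list alone), the median lying below 0 and the test direction above it. The monocyte median log2 fold change was -0.27, with a camera adjusted p = 0.96. F13a1 (2.14 ± 0.05) and Cd68 (1.16 ± 0.05) rose, and the complement gene C1qa fell (-4.63 ± 0.37). Dendritic cell genes had all 14 tested members lower (14 adjusted over the list alone), with Siglech at 0.0278 ± 0.0243 against 109.8 ± 2.86 CPM. The dendritic cell median log2 fold change was -6.34, with a camera adjusted p = 3.7e-09. MHC class II genes had 1 of 10 members higher and 8 lower (9 adjusted over the list alone). The MHC class II median log2 fold change was -7.44, with a camera adjusted p = 2.9e-06. The invariant chain Cd74 fell from 1122 ± 113 to 1.45 ± 0.714 CPM.

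Markers of other marrow lineages were lower in BN1. Early B cell genes had 1 of 20 members higher and 19 lower (20 adjusted over the list alone). The early B cell median log2 fold change was -8.54 (-7.58 with genes at their bound), with a camera adjusted p = 1.9e-14. Mature B and plasma cell genes had 1 of 17 members higher and 16 lower (17 adjusted over the list alone). The mature B cell median log2 fold change was -6.52, with a camera adjusted p = 9.8e-13. Cd79b fell to 2 counts over the group (8050-fold lower, counting interval 2230 to 66500), and Xbp1 rose (0.56 ± 0.04). T cell genes had all 15 tested members lower (15 adjusted over the list alone), with Cd2 at -8.96 ± 0.25. The T cell median log2 fold change was -8.51, with a camera adjusted p = 3e-11. NK cell genes had all 13 tested members lower (13 adjusted over the list alone), with Il2rb at -10.32 ± 0.22. The NK cell median log2 fold change was -8.83 (-7.95 with genes at their bound), with a camera adjusted p = 7.4e-09. Erythroid genes had all 19 tested members lower (19 adjusted over the list alone), such as the anion exchanger Slc4a1 (-12.24 ± 0.18). The erythroid median log2 fold change was -10.93, with a camera adjusted p = 6.9e-23. Megakaryocyte and platelet genes had 1 of 12 members higher and 11 lower (12 adjusted over the list alone), with integrin Itga2b at -6.63 ± 0.19. The megakaryocyte median log2 fold change was -4.71, with a camera adjusted p = 0.00072 (adjusted p = 0.084 with an estimated correlation). Eosinophil, basophil and mast cell genes had 1 of 15 members higher and 14 lower (15 adjusted over the list alone), with no counts of Prg2 (at least 618-fold lower). The eosinophil and basophil median log2 fold change was -7.15 (-5.39 with genes at their bound), with a camera adjusted p = 1.5e-08. Stromal and endothelial genes had 6 of 7 members lower and none higher (6 adjusted over the list alone). The stromal median log2 fold change was -2.51, with a camera adjusted p = 0.12.

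Cell cycle genes fell in BN1, with 3 of 28 members higher and 25 lower (28 adjusted over the list alone), among them Ccnd2 (-6.69 ± 0.16), Ube2c (-2.34 ± 0.08) and Ccna2 (-1.95 ± 0.06). The cell cycle median log2 fold change was -1.04, with a camera adjusted p = 5.9e-06 (adjusted p = 0.16 with an estimated correlation). Myc and ribosome biogenesis genes rose, with 18 of 20 members higher and 2 lower (20 adjusted over the list alone), for example the helicase Ddx21 (1.13 ± 0.04) and the pyrimidine enzyme Cad (1.04 ± 0.06), while Odc1 fell (-1.48 ± 0.05). The Myc and ribosome median log2 fold change was 0.71, with a camera adjusted p = 0.00023. Glycolysis genes had 8 of 15 members higher and 5 lower (13 adjusted over the list alone), with Pfkl higher (1.35 ± 0.06) and the lactate transporter Slc16a3 lower (-1.06 ± 0.06). The glycolysis median log2 fold change was 0.36, with a camera adjusted p = 0.22. Interferon response genes fell, with 2 of 19 members higher and 15 lower (17 adjusted over the list alone), including Rsad2 (-4.77 ± 0.07) and Oas3 (-4.32 ± 0.07), whereas Cxcl10 rose (1.61 ± 0.14). The interferon median log2 fold change was -1.77, with a camera adjusted p = 6.3e-06. The list of p53 targets and cell cycle inhibitors had 8 of 13 members higher and 5 lower (13 adjusted over the list alone), with Cdkn2a (4.97 ± 0.35) and Cdkn1a (1.88 ± 0.08) higher and Trp53inp1 lower (-1.23 ± 0.08). For this mixed list the median log2 fold change was 0.90, with a camera adjusted p = 0.12. Bcl2 family genes had 5 of 11 members higher and 4 lower (9 adjusted over the list alone), with a mean of -0.31; Bcl2 itself fell (-2.96 ± 0.09) and Bcl2l2 rose (1.27 ± 0.09). The Bcl2 family median log2 fold change was 0.11, with a camera adjusted p = 0.74. Immediate early and handling stress genes fell, with 3 of 19 members higher and 13 lower (16 adjusted over the list alone), Dusp1 at -4.52 ± 0.21 and Fos higher at 2.09 ± 0.21. The immediate early median log2 fold change was -1.31, with a camera adjusted p = 0.02 (adjusted p = 0.39 with an estimated correlation). Mitochondrially encoded genes had 2 of 13 members higher and none lower (2 adjusted over the list alone), ATP8 and ND3 being the members called. The mitochondrial median log2 fold change was 0.23, with a camera adjusted p = 0.35. The non-Hox MLL targets had a mean of -0.02, opposite in sign to their median.

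MLL-AF9 cells were next compared with normal marrow. Every tested gene of the HoxA cluster rose in MA9, with Hoxa9 at 360.4 ± 11.5 against 3.71 ± 0.178 CPM and Hoxa10 at 206 ± 9.85 against 0.248 ± 0.0693 CPM. Meis1 (chromosome 11, from 18880428 to 19019651) rose to 133 ± 6.56 CPM (4.22 ± 0.10). Mature neutrophil, red cell and lymphoid genes fell, with lactoferrin (Ltf) at 6.95 ± 0.857 against 9125 ± 66.4 CPM. Transcripts of both the X-linked RNA Xist and Y-linked genes were present in MA9 cells. Xist stood at 323 to 373 CPM in the MA9 libraries and at 755 to 981 CPM in all others, and the summed level of Ddx3y, Eif2s3y, Kdm5d and Uty at 149 to 165 CPM in MA9.

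In this comparison 12284 genes were called, 6033 higher and 6251 lower (6492 and 5875 with upper-quartile scaling), and 5929 changed by at least 2-fold (2279 higher and 3650 lower). The largest rises were of Stra6, a retinol transporter (at least 1170-fold higher), Six4 (at least 1120-fold higher) and Ppp1r14c (at least 550-fold higher). Y-linked genes followed, namely Ddx3y (at least 1050-fold higher), Eif2s3y (at least 933-fold higher), Kdm5d (at least 549-fold higher) and Uty (at least 354-fold higher). The largest falls were of the basophil protease Prss34 (at least 5490-fold lower) and the B cell gene Pou2af1 (at least 3280-fold lower). Red cell genes came next, namely Kel (at least 3020-fold lower), Slc4a1 (-14.53 ± 0.21), Btnl10 (at least 2480-fold lower), Epb42 (at least 2330-fold lower) and Car1 (at least 2200-fold lower). With X and Y genes left out, an alternative added after seeing the data, 11936 genes were called.

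The HoxA cluster had all 10 tested members higher (10 adjusted over the list alone). For HoxA genes the median log2 fold change was 5.81, with a camera adjusted p = 2.8e-09. HoxB genes had 1 of 7 members higher and 2 lower (3 adjusted over the list alone). For HoxB genes the median log2 fold change was -1.45, with a camera adjusted p = 0.96. Hoxb13 was higher at 5.54 ± 0.931 CPM, and Hoxb3 (-1.45 ± 0.22) and Hoxb4 (-1.23 ± 0.13) were lower. Non-Hox MLL targets rose, with 11 of 19 members higher and 4 lower (15 adjusted over the list alone), including Igf2bp3 (5.86 ± 0.10), whereas Bcl11a fell (-5.89 ± 0.12). For MLL target genes the median log2 fold change was 0.80, with a camera adjusted p = 0.00018. Stem cell genes fell, with 1 of 14 members higher and 10 lower (11 adjusted over the list alone), and Cdkn1c rose (5.81 ± 0.13). For stem cell genes the median log2 fold change was -3.62, with a camera adjusted p = 0.014 (adjusted p = 0.06 with an estimated correlation). Early progenitor genes had 10 of 17 members higher and 7 lower (17 adjusted over the list alone) and a mean of -0.65; Myb (2.01 ± 0.04), Myc (1.51 ± 0.06) and Adgrl4 (2.01 ± 0.09) rose, Cd34 stood at 46.1 ± 2.79 CPM, and Kit rose by 0.55 ± 0.06. For early progenitor genes the median log2 fold change was 0.43, with a camera adjusted p = 0.31. Primary granule genes rose, with 9 of 14 members higher and 3 lower (12 adjusted over the list alone), Elane at 4.06 ± 0.04 and Gfi1 at 3.47 ± 0.05. For primary granule genes the median log2 fold change was 1.61, with a camera adjusted p = 0.00057 (adjusted p = 0.12 with an estimated correlation). Mature neutrophil genes fell, with all 20 tested members lower (20 adjusted over the list alone), Retnlg at -11.79 ± 0.14 and Mmp9 at -7.73 ± 0.07. For neutrophil genes the median log2 fold change was -6.48, with a camera adjusted p = 1.1e-21. Monocyte and macrophage genes fell, with 5 of 23 members higher and 16 lower (21 adjusted over the list alone). For monocyte genes the median log2 fold change was -2.25, with a camera adjusted p = 0.001 (adjusted p = 0.056 with an estimated correlation). Fcgr1 was lower (-6.40 ± 0.21) and Vcam1 higher (1.42 ± 0.07).

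Lists of other lineages fell in MA9. Dendritic cell genes had all 14 tested members lower (14 adjusted over the list alone). For dendritic cell genes the median log2 fold change was -5.96, with a camera adjusted p = 1.4e-08. MHC class II genes had 1 of 10 members higher and 8 lower (9 adjusted over the list alone). For MHC class II genes the median log2 fold change was -3.71, with a camera adjusted p = 2.2e-05 (adjusted p = 0.062 with an estimated correlation). Early B cell genes had all 20 tested members lower (20 adjusted over the list alone). For early B cell genes the median log2 fold change was -5.92 (-5.85 with genes at their bound), with a camera adjusted p = 4.4e-14. Mature B and plasma cell genes had 1 of 17 members higher and 16 lower (17 adjusted over the list alone). For mature B cell genes the median log2 fold change was -7.65, with a camera adjusted p = 3.2e-10. T cell genes had all 15 tested members lower (15 adjusted over the list alone). For T cell genes the median log2 fold change was -5.42, with a camera adjusted p = 2.4e-09. NK cell genes had all 13 tested members lower (13 adjusted over the list alone). For NK cell genes the median log2 fold change was -8.03 (-7.38 with genes at their bound), with a camera adjusted p = 2.2e-08. Erythroid genes had all 19 tested members lower (19 adjusted over the list alone). For erythroid genes the median log2 fold change was -10.32, with a camera adjusted p = 7.9e-21. Megakaryocyte and platelet genes had all 12 tested members lower (12 adjusted over the list alone). For megakaryocyte genes the median log2 fold change was -3.97, with a camera adjusted p = 0.00047 (adjusted p = 0.089 with an estimated correlation). Eosinophil, basophil and mast cell genes had 2 of 15 members higher and 13 lower (15 adjusted over the list alone), with Siglecf higher (2.32 ± 0.11). For eosinophil and basophil genes the median log2 fold change was -5.75 (-4.13 with genes at their bound), with a camera adjusted p = 5.3e-06. Myc and ribosome biogenesis genes rose, with 19 of 20 members higher and 1 lower (20 adjusted over the list alone), led by spermidine synthase (Srm, 2.03 ± 0.07) and Bop1 (1.64 ± 0.05). For Myc and ribosome genes the median log2 fold change was 1.23, with a camera adjusted p = 2.8e-10. Glycolysis genes rose, with 11 of 15 members higher and 3 lower (14 adjusted over the list alone), for example Pgam1 (1.43 ± 0.04). For glycolysis genes the median log2 fold change was 0.26, with a camera adjusted p = 0.0097 (adjusted p = 0.31 with an estimated correlation). Interferon response genes fell, with 18 of 19 members lower and none higher (18 adjusted over the list alone), and Rsad2 was at -7.29 ± 0.10. For interferon genes the median log2 fold change was -2.62, with a camera adjusted p = 1.1e-09. Immediate early and handling stress genes fell, with 3 of 19 members higher and 13 lower (16 adjusted over the list alone), Btg2 at -3.65 ± 0.06. For immediate early genes the median log2 fold change was -1.40, with a camera adjusted p = 0.00061 (adjusted p = 0.24 with an estimated correlation). The remaining 9 lists, HoxB among them, were not separated from other genes (camera adjusted p from 0.13 to 0.96). Median, mean and test differed in sign for the 10p12 counterparts, early progenitors, p53 targets and the Bcl2 family. Among stromal and endothelial genes, a list not separated, Pdgfrb (2.30 ± 0.15) and Cxcl12 (1.92 ± 0.30) were higher and Cdh5 was lower (-6.23 ± 0.43).

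MLL-ENL cells were compared with normal marrow to ask the same of the second MLL fusion. The HoxA cluster rose in ME, with Hoxa9 at 286 ± 5.41 CPM (6.26 ± 0.07) and Hoxa10 at 216 ± 9.47 CPM, and Meis1 rose to 36.9 ± 3.34 CPM (2.37 ± 0.11). Myb, a transcription factor of blood progenitors, rose from 201 ± 1.26 to 1139 ± 31.4 CPM and Myc from 48.2 ± 2.79 to 153 ± 12.1 CPM. Elane (4.28 ± 0.04) and the azurophil protease Prtn3 (3.71 ± 0.05) rose, whereas the secondary granule genes Ltf (-13.78 ± 0.09) and Ngp (-10.72 ± 0.06) fell. Cd34 fell from 28.5 ± 1.73 to 3.42 ± 0.985 CPM and Kit rose to 154 ± 9.15 CPM.

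Of the genes tested, 12152 were called in ME against WT, 5982 higher and 6170 lower (6311 and 5903 with upper-quartile scaling), and 5795 changed by at least 2-fold (2132 higher and 3663 lower). Leaving out ME replicate 3, the library with the structural RNA-like reads, gave 12155. The largest rises were of Hoxa11 (at least 597-fold higher), Hpse2 (5420-fold higher, counting interval 973 to 214000) and the myelin protein gene Pmp22 (4910-fold higher, counting interval 881 to 194000). LOC108168967 (at least 352-fold higher), the receptor phosphatase Ptprt (2840-fold higher, counting interval 509 to 112000), Dmrtb1 (10.82 ± 0.12), Snhg11 (1900-fold higher, counting interval 341 to 75200) and AF357359 (at least 137-fold higher) followed. The largest falls were of the red cell genes Slc4a1 (at least 32900-fold lower), Hbb-bt (-15.60 ± 0.36) and Trim10 (at least 2960-fold lower). Falls of the B cell gene Pax5 (at least 3210-fold lower) and of Prss34 (at least 5240-fold lower) belonged here as well.

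HoxA genes had all 10 tested members higher (10 adjusted over the list alone). The HoxA median log2 fold change was 5.16, with a camera adjusted p = 6.5e-10. HoxB genes had 1 of 7 members higher and 2 lower (3 adjusted over the list alone), with Hoxb4 lower (-4.91 ± 0.22). The HoxB median log2 fold change was -2.81, with a camera adjusted p = 0.69. Non-Hox MLL targets had 10 of 19 members higher and 8 lower (19 adjusted over the list alone). The MLL target median log2 fold change was 0.51, with a camera adjusted p = 0.13. Cdk6, a cell cycle kinase, rose (3.66 ± 0.05) and Bcl11a fell (-4.92 ± 0.11). Stem cell genes had 2 of 14 members higher and 11 lower (13 adjusted over the list alone), a list that was called when any single WT library was left out (adjusted p 0.024, 0.028 and 0.026); the imprinted RNA Meg3 rose (9.69 ± 0.28) and Gata2 fell (-6.40 ± 0.18). The stem cell median log2 fold change was -4.24 (-4.05 with genes at their bound), with a camera adjusted p = 0.065. Early progenitor genes had 7 of 17 members higher and 9 lower (16 adjusted over the list alone). The early progenitor median log2 fold change was -0.70, with a camera adjusted p = 0.69. Primary granule genes rose, with 10 of 14 members higher and 3 lower (14 adjusted over the list alone). The primary granule median log2 fold change was 1.62, with a camera adjusted p = 0.00031 (adjusted p = 0.11 with an estimated correlation). Mature neutrophil genes fell, with 1 of 20 members higher and 19 lower (20 adjusted over the list alone), except for Chil3 (2.04 ± 0.05). The neutrophil median log2 fold change was -4.89, with a camera adjusted p = 2.5e-21. Monocyte and macrophage genes fell, with 4 of 23 members higher and 18 lower (22 adjusted over the list alone). The monocyte median log2 fold change was -1.5, with a camera adjusted p = 0.00083. Cd14 was higher (1.47 ± 0.10) and Fcgr1 lower (-7.30 ± 0.24).

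The lists of other lineages fell in ME too. Dendritic cell genes had all 14 tested members lower (14 adjusted over the list alone). The dendritic cell median log2 fold change was -6.64 (-6.55 with genes at their bound), with a camera adjusted p = 4.6e-09. MHC class II genes had 1 of 10 members higher and 8 lower (9 adjusted over the list alone). The MHC class II median log2 fold change was -4.76, with a camera adjusted p = 1.2e-06. Early B cell genes had 1 of 20 members higher and 19 lower (20 adjusted over the list alone). The early B cell median log2 fold change was -8.09 (-7.31 with genes at their bound), with a camera adjusted p = 1.6e-15. Mature B and plasma cell genes had 1 of 17 members higher and 16 lower (17 adjusted over the list alone). The mature B cell median log2 fold change was -8.17 (-8.00 with genes at their bound), with a camera adjusted p = 4.2e-12. T cell genes had all 15 tested members lower (15 adjusted over the list alone). The T cell median log2 fold change was -7.24, with a camera adjusted p = 1.3e-10. NK cell genes had all 13 tested members lower (13 adjusted over the list alone). The NK cell median log2 fold change was -9.59 (-7.44 with genes at their bound), with a camera adjusted p = 6.4e-09. Erythroid genes had all 19 tested members lower (19 adjusted over the list alone). The erythroid median log2 fold change was -12.97 (-11.04 with genes at their bound), with a camera adjusted p = 6.1e-25. Megakaryocyte and platelet genes had all 12 tested members lower (12 adjusted over the list alone). The megakaryocyte median log2 fold change was -4.09 (-3.30 with genes at their bound), with a camera adjusted p = 0.00073 (adjusted p = 0.096 with an estimated correlation). Eosinophil, basophil and mast cell genes had 1 of 15 members higher and 14 lower (15 adjusted over the list alone). The eosinophil and basophil median log2 fold change was -7.15 (-6.22 with genes at their bound), with a camera adjusted p = 1.8e-07. Myc and ribosome biogenesis genes rose, with 19 of 20 members higher and 1 lower (20 adjusted over the list alone). The Myc and ribosome median log2 fold change was 1.17, with a camera adjusted p = 7.4e-10. Glycolysis genes rose, with 11 of 15 members higher and 3 lower (14 adjusted over the list alone). The glycolysis median log2 fold change was 0.50, with a camera adjusted p = 0.0012 (adjusted p = 0.22 with an estimated correlation). Interferon response genes fell, with 2 of 19 members higher and 17 lower (19 adjusted over the list alone). The interferon median log2 fold change was -1.58, with a camera adjusted p = 1.8e-07. Immediate early genes fell, with 2 of 19 members higher and 14 lower (16 adjusted over the list alone). The immediate early median log2 fold change was -1.29, with a camera adjusted p = 0.00083 (adjusted p = 0.25 with an estimated correlation). Camera separated none of the other 11 lists (adjusted p from 0.065 to 0.9), and the p53 targets had a median of -0.58 and a mean of 0.06.

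**Figure D1:**
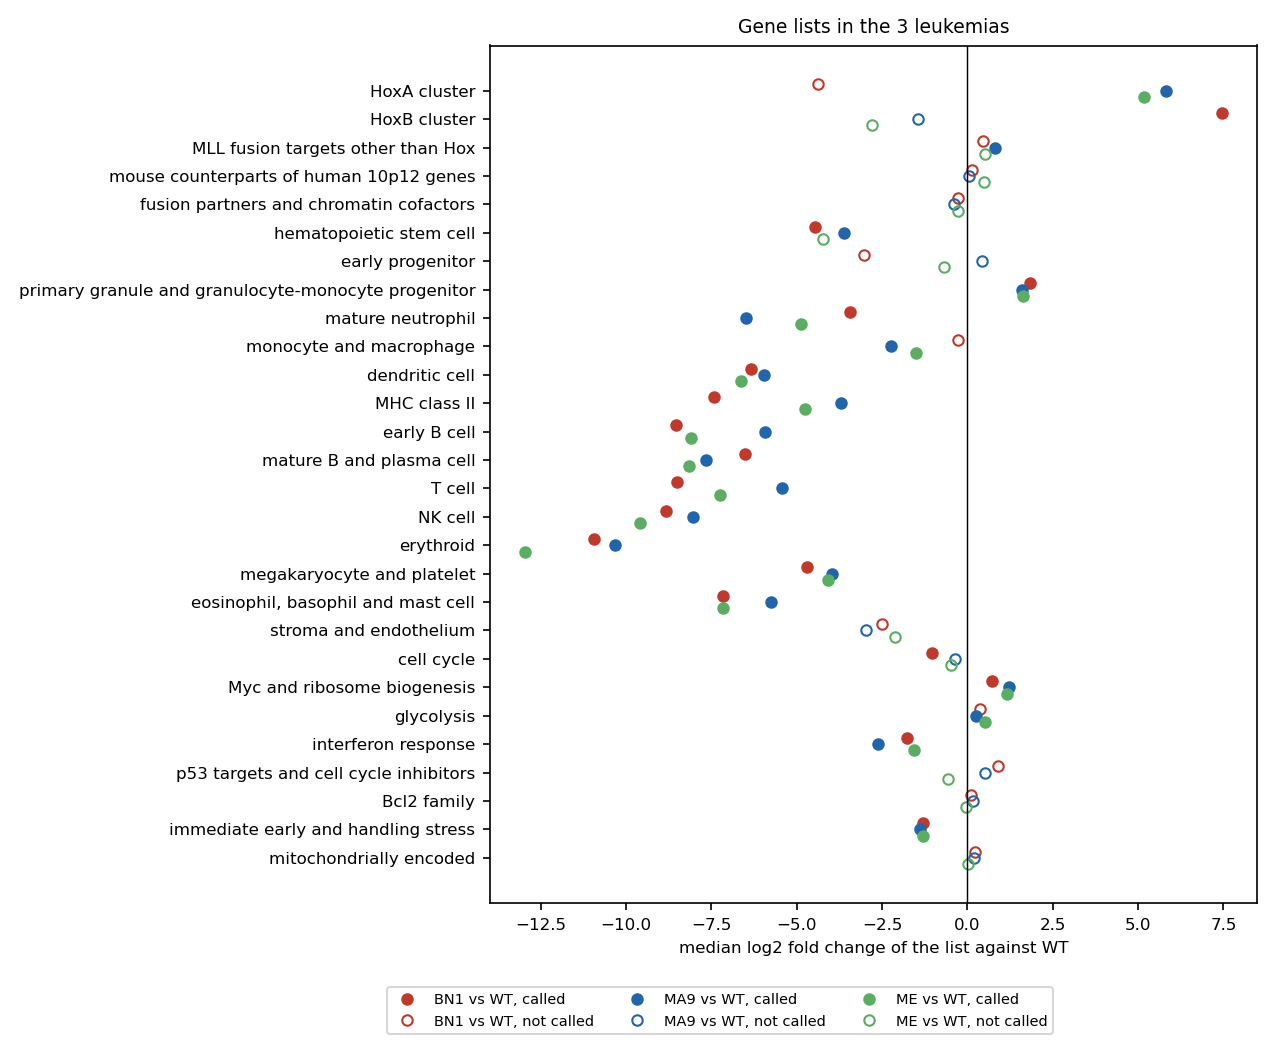
Median log2 fold change against WT (horizontal axis) of the 28 gene lists fixed before the data were examined, for BN1, MA9 and ME; filled points are lists called by camera. The HoxA median lies at -4.38 in BN1, 5.81 in MA9 and 5.16 in ME, and the HoxB median at 7.46, -1.45 and -2.81.

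Calls against WT overlapped between the leukemias. BN1 and MA9 shared 4282 genes higher and 4791 lower, where independent lists of these sizes would share 2316 and 2552, and 1244 genes were called in opposite directions (4862 for independent lists). BN1 and ME shared 4326 higher and 4867 lower (2296 and 2519), with 1123 opposite (4810), and MA9 and ME shared 5100 higher and 5471 lower (2354 and 2515), with 366 opposite (4866). In all 3 leukemias 3887 genes were higher and 4475 lower. Unchanged groups simulated against the WT libraries shared a median of 0 called genes at the adjusted threshold in edgeR, and 150.5, 144.5 and 143.5 genes for the pairs in the same order at an unadjusted p under 0.05. Correlations of the log2 fold changes across genes, which are not independent replicates, were 0.76, 0.79 and 0.88 for these pairs, against 0.52, 0.51 and 0.50 in the simulations. The covariances were 5.05, 5.42 and 5.80 against a simulated 0.017 (differences 5.03, 5.40 and 5.78), so shared WT noise explained little. The 3 WT libraries cannot form separate controls of at least 2 each, and shared loss of WT lineages may add overlap.

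BRD9-NUTM1 cells were compared directly with MLL-AF9 cells, which asks how far the NUTM1 fusion resembles a reference MLL leukemia. The Hox clusters went in opposite directions: Hoxb5, Hoxb6 and Hoxb8 had no counts in MA9 and stood at 62.5 ± 3.99, 25.4 ± 1.27 and 28.0 ± 0.603 CPM in BN1, whereas Hoxa10 had none in BN1 and stood at 206 ± 9.85 CPM in MA9. Hoxa9 gave 1 count over the BN1 libraries against 360.4 ± 11.5 CPM in MA9, and Meis1 gave 0.126 ± 0.115 against 133 ± 6.56 CPM. Flt3, the receptor of a growth factor for early progenitors (-9.83 ± 0.17), and Cd34, a surface protein of stem and progenitor cells (-6.27 ± 0.17), were lower in BN1. The secondary granule gene lactoferrin was higher in BN1, at 1128 ± 14.1 against 6.95 ± 0.857 CPM, as was the myeloid gene lysozyme (Lyz2) at 9059.8 ± 218 against 818 ± 8.48 CPM. MA9 libraries also held Y-linked transcripts, and with X and Y genes left out 10067 genes were called.

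In all, 10375 genes were called, 5028 higher and 5347 lower in BN1, and 3649 differed by at least 2-fold (1692 higher and 1957 lower). Largest on the BN1 side were Marco (at least 1690-fold higher), Hoxb5 (at least 1330-fold higher), Hoxb8 (at least 595-fold higher) and Hoxb6 (at least 539-fold higher). Sestd1 (2620-fold higher, counting interval 470 to 104000), Fam167b (at least 147-fold higher), the matrix protein periostin (Postn, at least 136-fold higher) and Zkscan2 (1280-fold higher, counting interval 230 to 50700) followed. On the MA9 side they were Hoxa10 (at least 4990-fold lower in BN1), Hoxa9 (26200-fold lower, counting interval 4710 to 1040000), Eya1, a transcriptional cofactor (at least 1940-fold lower), and the transcription factor Helios (Ikzf2, at least 1900-fold lower). Stra6 (at least 1520-fold lower), Dach1 (at least 811-fold lower), Ddx3y (at least 1360-fold lower) and Eif2s3y (at least 1210-fold lower) followed.

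HoxA genes were lower in BN1, with 1 of 10 members higher and 9 lower (10 adjusted over the list alone). For HoxA genes the median log2 fold change was -11.33 (-9.05 with genes at their bound), with a camera adjusted p = 2e-09. HoxB genes were higher, with 6 of 7 members higher and 1 lower (7 adjusted over the list alone). For HoxB genes the median log2 fold change was 8.41, with a camera adjusted p = 2.4e-05 (adjusted p = 0.054 with an estimated correlation). Non-Hox MLL targets were lower, with 5 of 19 members higher and 13 lower (18 adjusted over the list alone). For MLL target genes the median log2 fold change was -0.95, with a camera adjusted p = 0.00033 (adjusted p = 0.054 with an estimated correlation). Six4 (-3.11 ± 0.10) was lower and Bcl11a (6.33 ± 0.12) and Hmga2 (3.98 ± 0.13) were higher. Early progenitor genes were lower, with 5 of 17 members higher and 11 lower (16 adjusted over the list alone), although Kit was higher (0.73 ± 0.05). For early progenitor genes the median log2 fold change was -1.86 (-1 with genes at their bound), with a camera adjusted p = 0.0067 (adjusted p = 0.054 with an estimated correlation). Mature neutrophil genes were higher, with 17 of 20 members higher and 3 lower (20 adjusted over the list alone), such as Retnlg (7.39 ± 0.14) and Fpr1 (6.62 ± 0.23). For neutrophil genes the median log2 fold change was 2.99, with a camera adjusted p = 5e-13. Monocyte and macrophage genes were higher, with 14 of 23 members higher and 5 lower (19 adjusted over the list alone), such as the mannose receptor Mrc1 (4.20 ± 0.21). For monocyte genes the median log2 fold change was 1.21, with a camera adjusted p = 0.00097 (adjusted p = 0.085 with an estimated correlation). Cell cycle genes were lower, with 2 of 28 members higher and 25 lower (27 adjusted over the list alone), including Rrm2 (-1.26 ± 0.05) and Plk1 (-1.18 ± 0.06), and Ccnd1 was higher (2.40 ± 0.16). For cell cycle genes the median log2 fold change was -0.81, with a camera adjusted p = 2.6e-08 (adjusted p = 0.13 with an estimated correlation). Myc and ribosome biogenesis genes were lower, with all 20 tested members lower (20 adjusted over the list alone). For Myc and ribosome genes the median log2 fold change was -0.60, with a camera adjusted p = 3.1e-07. Myc itself stood at 71.8 ± 3.32 against 137 ± 6.30 CPM. Interferon response genes were higher, with 13 of 19 members higher and 2 lower (15 adjusted over the list alone), for example Cxcl10 (3.50 ± 0.17). For interferon genes the median log2 fold change was 0.85, with a camera adjusted p = 0.00052 (adjusted p = 0.054 with an estimated correlation). The list of p53 targets and cell cycle inhibitors was higher, with 9 of 13 members higher and 2 lower (11 adjusted over the list alone), Cdkn2c at 3.37 ± 0.08 and Cdkn2a lower at -1.73 ± 0.15. For this mixed list the median log2 fold change was 0.48, with a camera adjusted p = 0.016 (adjusted p = 0.13 with an estimated correlation). The other 18 lists had camera adjusted p from 0.051 to 0.9; the lowest was that of MHC class II, with 8 of 10 members lower, and its call changed with the libraries used (0.03 to 0.045 in 4 of the fits with 1 library left out). Median, mean and test differed in sign for mature B cell and erythroid genes.

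**Figure D2:**
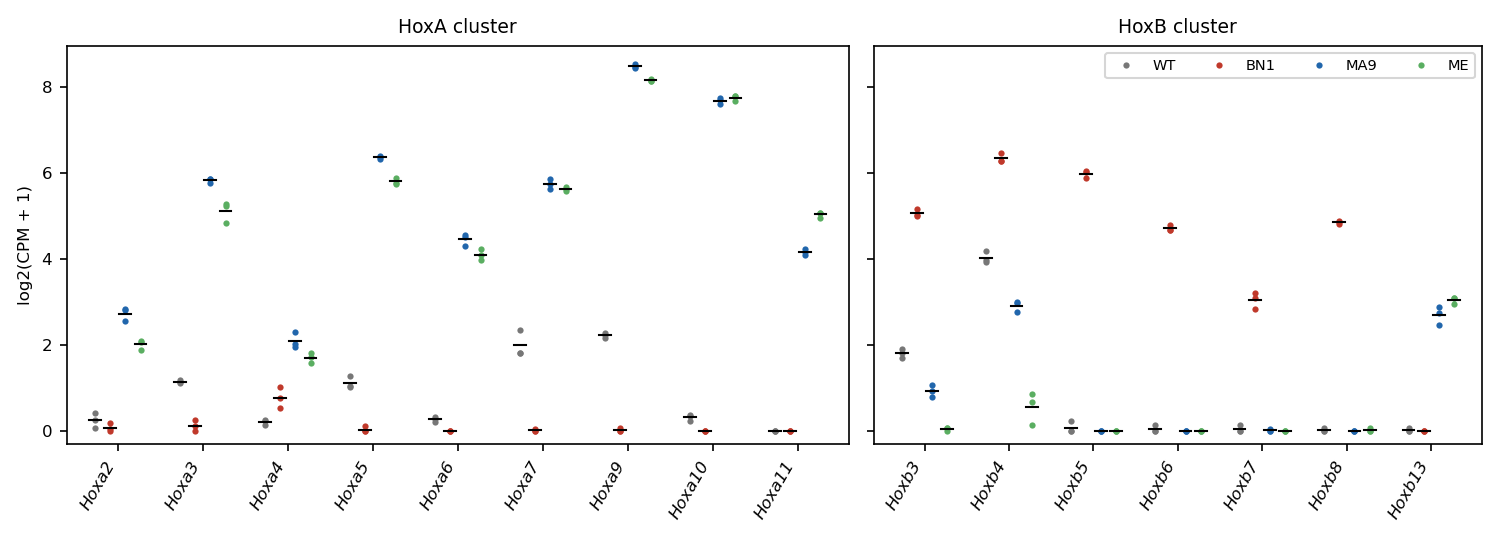
Expression of HoxA and HoxB genes as log2(CPM + 1) (vertical axis) in each of the 12 libraries, with bars at the group means. HoxA genes such as Hoxa9 and Hoxa10 are high in MA9 and ME, and HoxB genes such as Hoxb4 and Hoxb5 are high in BN1.

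The same question was put for MLL-ENL. Hoxb5, Hoxb6 and Hoxb7 had no counts in ME, Hoxa10 had none in BN1, and Meis1 (-8.15 ± 0.20) and Flt3 (-7.29 ± 0.22) were lower in BN1. The mature neutrophil genes Ltf (10.77 ± 0.09), Ngp (6.55 ± 0.06) and S100a9 (5.40 ± 0.05) were higher in BN1 than in ME. Myc stood at 71.8 ± 3.32 CPM in BN1 and 153 ± 12.1 in ME, and Kit at 126 ± 1.27 and 154 ± 9.15 CPM. Chil3, a secreted chitinase-like protein of myeloid cells, was abundant in both groups, at 18764 ± 877 CPM in BN1 and 16124 ± 1230 in ME, against 1642 ± 79.6 in MA9.

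There were 9927 called genes, 4871 higher and 5056 lower in BN1, of which 3391 differed by at least 2-fold (1731 higher and 1660 lower), and 9670 were called without ME replicate 3. Largest on the BN1 side were Hoxb5 (at least 1270-fold higher), Hoxb6 (at least 515-fold higher) and Marco (4840-fold higher, counting interval 868 to 191000). Zkscan2 (at least 409-fold higher), Lhfp (at least 315-fold higher), Hoxb5os (at least 293-fold higher), Amigo2 (at least 234-fold higher) and Ltf came next. Largest on the ME side were Hoxa10 (at least 5230-fold lower in BN1), Hoxa9 (20700-fold lower, counting interval 3720 to 819000), Ptprt (at least 1230-fold lower) and Dach1 (at least 928-fold lower). Hoxa11 (at least 774-fold lower), Hpse2 (7040-fold lower, counting interval 1260 to 278000), Meg3 (4510-fold lower, counting interval 1250 to 37300) and Hoxa6 (at least 394-fold lower) came next.

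Against ME, HoxA genes were lower in BN1, with 9 of 10 members lower and none higher (10 adjusted over the list alone). The HoxA median log2 fold change was -10.98 (-9.11 with genes at their bound), with a camera adjusted p = 3e-10. HoxB genes were higher, with 6 of 7 members higher and 1 lower (7 adjusted over the list alone). The HoxB median log2 fold change was 10.27 (9.01 with genes at their bound), with a camera adjusted p = 7.6e-06 (adjusted p = 0.051 with an estimated correlation). Early progenitor genes were lower, with 4 of 17 members higher and 12 lower (16 adjusted over the list alone), Adgrl4 at -4.38 ± 0.12 and Cd93 higher at 1.18 ± 0.04. The early progenitor median log2 fold change was -1.09, with a camera adjusted p = 0.012 (adjusted p = 0.066 with an estimated correlation). Mature neutrophil genes were higher, with 17 of 20 members higher and 2 lower (19 adjusted over the list alone), apart from Il1r2 (-3.81 ± 0.12) and Itgam (-0.48 ± 0.04). The neutrophil median log2 fold change was 2.17, with a camera adjusted p = 1.6e-11. Monocyte and macrophage genes were higher, with 17 of 23 members higher and 3 lower (21 adjusted over the list alone), such as Mrc1 (2.79 ± 0.17), and Cd14 was lower (-1.77 ± 0.10). The monocyte median log2 fold change was 1.28, with a camera adjusted p = 8.3e-06. Cell cycle genes were lower, with 2 of 28 members higher and 26 lower (28 adjusted over the list alone). The cell cycle median log2 fold change was -0.71, with a camera adjusted p = 2.8e-08 (adjusted p = 0.15 with an estimated correlation). Myc and ribosome biogenesis genes were lower, with 1 of 20 members higher and 17 lower (19 adjusted over the list alone). The Myc and ribosome median log2 fold change was -0.48, with a camera adjusted p = 7.6e-06. Glycolysis genes were lower, with 2 of 15 members higher and 12 lower (14 adjusted over the list alone), Ldha at -0.82 ± 0.04, while Hk2 was higher (0.69 ± 0.06). The glycolysis median log2 fold change was -0.47, with a camera adjusted p = 0.003 (adjusted p = 0.39 with an estimated correlation). The p53 target and cell cycle inhibitor list was higher, with 11 of 13 members higher and 2 lower (13 adjusted over the list alone), Cdkn2c at 2.80 ± 0.07. For this mixed list the median log2 fold change was 0.50, with a camera adjusted p = 0.0074 (adjusted p = 0.086 with an estimated correlation). Non-Hox MLL targets had 8 of 19 members higher and 9 lower (17 adjusted over the list alone), with Six4 (141-fold higher, counting interval 47.9 to 685) higher in BN1. The MLL target median log2 fold change was -0.29, with a camera adjusted p = 0.76. Interferon response genes went both ways, with Cxcl10 higher (2.68 ± 0.15) and Oas3 lower (-1.48 ± 0.07), and the list had a camera adjusted p = 0.76. The 19 lists not called had adjusted p from 0.1 to 0.98 in camera, and signs differed between median, mean and test for the 10p12 counterparts, dendritic and mature B cell genes and the Bcl2 family, while the medians of T cell, NK cell, megakaryocyte and eosinophil lists were 0.

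**Figure D3:**
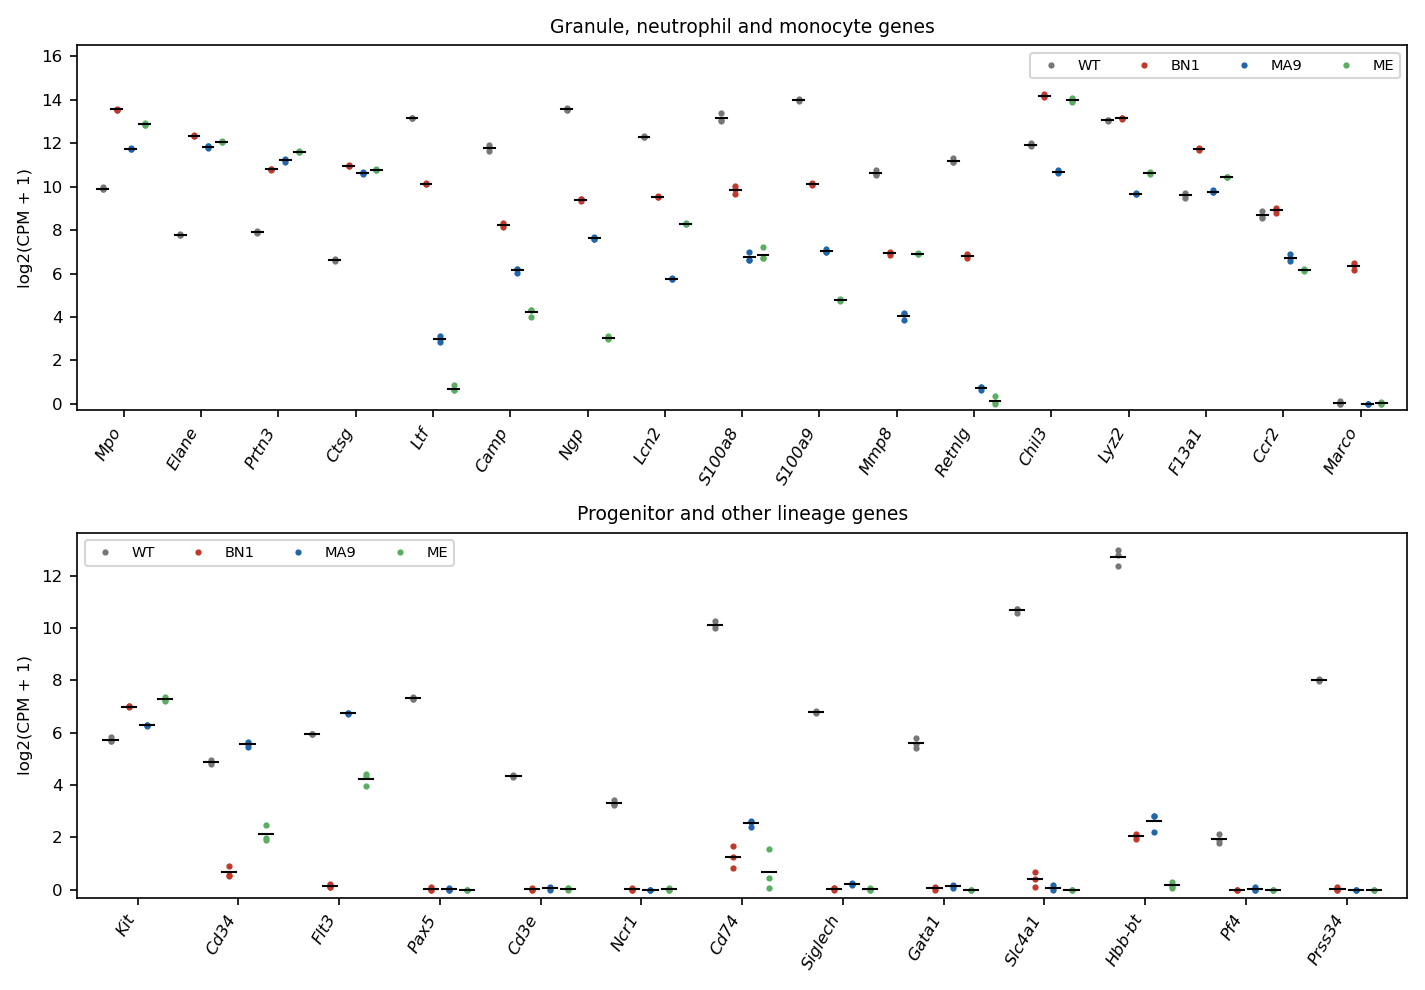
Expression as log2(CPM + 1) (vertical axis) of granule, neutrophil and monocyte genes (first panel) and of progenitor and lineage genes (second panel) in each of the 12 libraries, with bars at the group means. Chil3 is high in BN1 and ME, lactoferrin (Ltf) is lower in MA9 and ME than in BN1, and red cell and B cell genes are high in WT.

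The MLL-AF9 and MLL-ENL leukemias were compared with each other as a scale for differences within one class. Six4 (1220-fold higher, counting interval 416 to 5900) and Eya1, transcriptional regulators that act together in development, were higher in MA9, with Eya1 at 80.1 ± 3.76 CPM and without counts in ME. Cd34 stood at 46.1 ± 2.79 CPM in MA9 and 3.42 ± 0.985 in ME (3.77 ± 0.13), and Meis1 at 133 ± 6.56 and 36.9 ± 3.34 CPM. The imprinted RNAs Meg3, at 123 ± 23.7 against 0.0324 ± 0.0561 CPM, and Rian (-11.03 ± 0.17) were higher in ME. Chil3 (-3.30 ± 0.05) and Mpo (-1.13 ± 0.04) were lower in MA9, and Ngp (4.77 ± 0.05) was higher.

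Fewer genes were called here, 6225, of which 3095 were higher and 3130 lower in MA9 (3376 and 2883 with upper-quartile scaling) and 1907 differed by at least 2-fold (1090 higher and 817 lower), and 5865 were called without ME replicate 3. Largest on the MA9 side were Eya1 (at least 1620-fold higher), Stra6 (at least 1270-fold higher), Lhfp (at least 616-fold higher) and Ppp1r14c (at least 596-fold higher). Gal3st1 (at least 356-fold higher), Rps4l (at least 199-fold higher), Lipo3 (2240-fold higher, counting interval 401 to 88400) and Ikzf2 (10.09 ± 0.24) came next. Largest on the ME side were Meg3 (3960-fold lower, counting interval 1090 to 32700), Rian and AF357359 (at least 156-fold lower in MA9). Sestd1 (942-fold lower, counting interval 169 to 37300), Capn11 (611-fold lower, counting interval 109 to 24200), Eps8l1 (325-fold lower, counting interval 89.7 to 2690), Cpne8 (-7.40 ± 0.27) and Nrap (-7.28 ± 0.19) came next.

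Camera called 4 lists between MA9 and ME. Interferon response genes were lower in MA9, with 1 of 19 members higher and 14 lower (15 adjusted over the list alone), including Ifit1 (-2.25 ± 0.18) and Rsad2 (-2.05 ± 0.15). For interferon genes the median log2 fold change was -0.79, with a camera adjusted p = 5.8e-08. Non-Hox MLL targets were called higher, with 9 of 19 members higher and 8 lower (17 adjusted over the list alone). For MLL target genes the median log2 fold change was 0.04, with a camera adjusted p = 0.0046 (adjusted p = 0.2 with an estimated correlation). The mean was 1.76, and members with large rises included Eya1 and Six4, while Hmga2 was lower (-2.52 ± 0.15). Early progenitor genes were higher, with 11 of 17 members higher and 5 lower (17 adjusted over the list alone), Flt3 at 2.54 ± 0.08 and Kit lower at -1.01 ± 0.05. For early progenitor genes the median log2 fold change was 0.53, with a camera adjusted p = 0.022 (adjusted p = 0.16 with an estimated correlation). Erythroid genes were called higher, with 6 of 19 members higher and none lower (6 adjusted over the list alone). For erythroid genes the median log2 fold change was 1.12 (0.61 with genes at their bound), with a camera adjusted p = 0.043 (adjusted p = 0.61 with an estimated correlation). The members that differed were mainly haemoglobin genes at trace level, such as Hbb-bs at 8.22 ± 1.42 CPM in MA9 and 0.566 ± 0.155 in ME against 10446 ± 1250 in WT, and without MA9 replicate 3 the adjusted p was 0.052. HoxA genes had 5 of 10 members higher and 2 lower (8 adjusted over the list alone), with Hoxa3 higher (0.72 ± 0.10) and Hoxa11 lower (-0.91 ± 0.10). For HoxA genes the median log2 fold change was 0.36, with a camera adjusted p = 0.27. HoxB genes had 2 of 7 members higher and none lower (2 adjusted over the list alone). For HoxB genes the median log2 fold change was 0.00, with a camera adjusted p = 0.28. Mature neutrophil genes had 8 of 20 members higher and 9 lower (17 adjusted over the list alone). For neutrophil genes the median log2 fold change was -0.06, with a camera adjusted p = 0.67. The 24 lists not called had adjusted p from 0.16 to 0.84 in camera, and signs differed for cofactor, monocyte, Bcl2 family and immediate early genes, while the medians of HoxB, stem cell and p53 target genes were 0.

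Against the mean of MA9 and ME, 10579 genes were called in BN1, 5230 higher and 5349 lower (5313 and 5267 with DESeq2 size factors), and 3470 differed by at least 2-fold (1719 higher and 1751 lower). Hoxb5 (at least 2590-fold higher), Marco (9910-fold higher, counting interval 1780 to 391000), Hoxb6 (at least 1050-fold higher) and Hoxb8 (3490-fold higher, counting interval 626 to 138000) led one side. Zkscan2 (2510-fold higher, counting interval 449 to 99100), Gpr119 (9.54 ± 0.23), Hoxb7 (916-fold higher, counting interval 164 to 36200) and Hoxb5os (9.11 ± 0.29) followed. Hoxa10 (at least 5110-fold lower), Hoxa9 (23500-fold lower, counting interval 4230 to 930000), and Dach1 (at least 869-fold lower) led the other. Hpse2 (6260-fold lower, counting interval 1120 to 247000), Ptprt (at least 751-fold lower), Hoxa11 (at least 593-fold lower), Hoxa6 (at least 453-fold lower) and Hoxa7 (3700-fold lower, counting interval 663 to 146000) followed. HoxA genes were lower, with 1 of 10 members higher and 9 lower (10 adjusted over the list alone). The HoxA median log2 fold change was -11.15 (-9.02 with genes at their bound), with a camera adjusted p = 3.3e-09. HoxB genes were higher, with 6 of 7 members higher and 1 lower (7 adjusted over the list alone). The HoxB median log2 fold change was 9.34, with a camera adjusted p = 1.1e-05 (adjusted p = 0.09 with an estimated correlation). Neutrophil genes were higher, with 17 of 20 members higher and 3 lower (20 adjusted over the list alone). The neutrophil median log2 fold change was 3.06, with a camera adjusted p = 5.3e-13. Monocyte and macrophage genes were higher, with 15 of 23 members higher and 4 lower (19 adjusted over the list alone). The monocyte median log2 fold change was 1.24, with a camera adjusted p = 0.00012 (adjusted p = 0.076 with an estimated correlation). Early progenitor genes were lower, with 5 of 17 members higher and 11 lower (16 adjusted over the list alone). The early progenitor median log2 fold change was -1.43 (-1.02 with genes at their bound), with a camera adjusted p = 0.015 (adjusted p = 0.089 with an estimated correlation). Cell cycle genes were lower, with 2 of 28 members higher and 25 lower (27 adjusted over the list alone). The cell cycle median log2 fold change was -0.72, with a camera adjusted p = 7.2e-09 (adjusted p = 0.13 with an estimated correlation). Myc and ribosome biogenesis genes were lower, with 19 of 20 members lower and none higher (19 adjusted over the list alone). The Myc and ribosome median log2 fold change was -0.55, with a camera adjusted p = 5e-07. Glycolysis genes were lower, with 3 of 15 members higher and 11 lower (14 adjusted over the list alone). The glycolysis median log2 fold change was -0.36, with a camera adjusted p = 0.01 (adjusted p = 0.48 with an estimated correlation). The p53 target and cell cycle inhibitor list was higher, with 10 of 13 members higher and 2 lower (12 adjusted over the list alone). For this mixed list the median log2 fold change was 0.78, with a camera adjusted p = 0.0098 (adjusted p = 0.098 with an estimated correlation). Of all camera calls, those that held with an estimated correlation numbered 12 in BN1 against WT, 12 in MA9 against WT, 13 in ME against WT, 3 in BN1 against MA9 (HoxA, neutrophil and Myc), 4 in BN1 against ME (also monocyte), 1 in MA9 against ME (interferon) and 3 in BN1 against both. Uncalled lists, 19 in number, had camera adjusted p from 0.054 to 0.91, and signs differed between median, mean and test for dendritic and mature B cell genes and the Bcl2 family, while the medians of NK cell and eosinophil lists were 0.

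A block of zinc finger genes on chromosome 2, from 175275125 to 177479194, was examined after its values were seen. The 18 block genes with at least 1 CPM in WT, among them the zinc finger genes Zfp966, Zfp967 and Zfp968, were all under 0.5 CPM in BN1. Their summed level was 119 CPM in WT, 2.3 in BN1, 82.4 in MA9 and 177 in ME, and 168 counts fell on the block in BN1. The members 2210418O10Rik and Gm14296 were also under 0.5 CPM in ME, at 0.175 and 0 CPM. The neighbouring genes Gm14391, Gm14325, Gm14326 and Zfp971 summed to 94.0 CPM in WT, 95.4 in BN1, 61.3 in MA9 and 92.2 in ME.

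**Figure D4:**
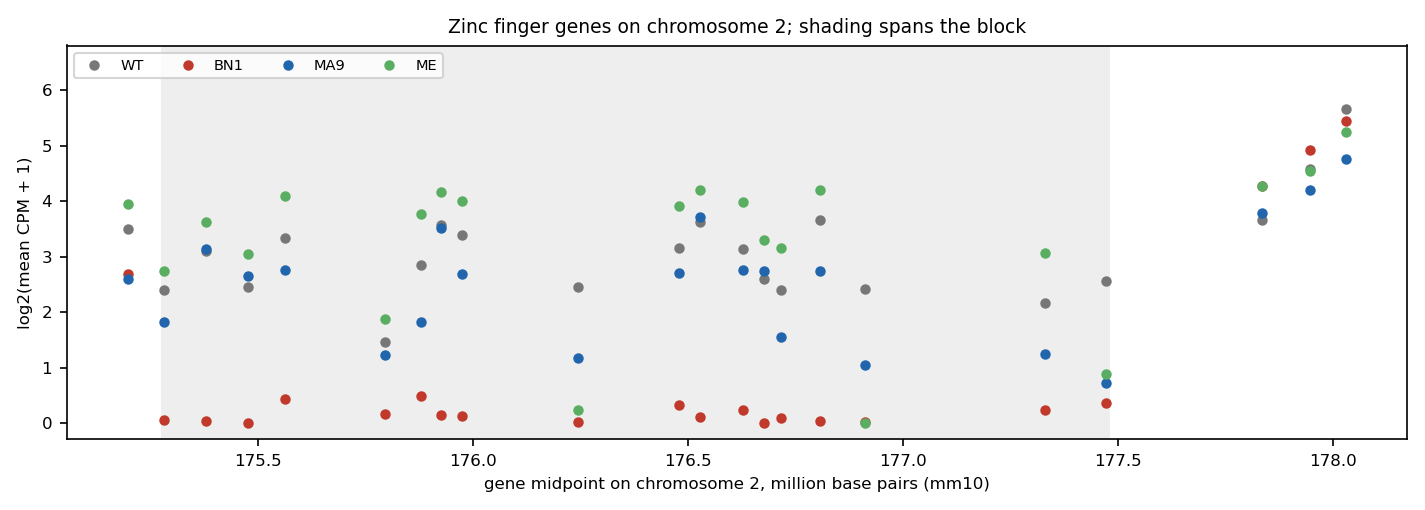
Group mean expression as log2(CPM + 1) (vertical axis) of zinc finger genes against gene midpoint on chromosome 2 in Mb of mm10 (horizontal axis) for WT, BN1, MA9 and ME; the shaded part is the block. The 18 block genes lie under 0.5 CPM in BN1.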

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

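The tests of explanations in this part were chosen only after the results were seen, and so were their limits.

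HoxA genes were nearly silent and HoxB genes active in BN1, and the reverse held in MA9 and ME. Summed HoxB levels in MA9 and ME were at most 5.51% of the BN1 level, which argues against HoxA reads counted at HoxB genes. The HoxB sum in BN1 was 13 times that of WT, which argues against residual normal marrow as the source. An exchange of whole groups could not be told apart from a true difference, since Nutm1 was highest in MA9 at 6.27 CPM and the species of the construct is not stated.

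Every MA9 library held Xist and Y-linked transcripts together. The highest Xist level of MA9 was 49.5% of the lowest library elsewhere. This value restates the pattern that raised the idea of male and female cells together in each MA9 library, so it does not test that idea, for which 60.7% of cells without Xist would be needed. The 4 Y-linked genes elsewhere reached 0.304% of the MA9 level, which argues against misplaced X-linked reads. B cell, T cell and erythroid genes stood in MA9 at a median of 0.208% of WT, which argues against normal male marrow cells. Pooling of animals or mixed donors may be the source, and neither was tested.

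The zinc finger block on chromosome 2 was near 0 in BN1. Against the mean of WT, MA9 and ME, its kept neighbours gained 10.4% of the CPM that the block lost, which argues against reads passed on to them. Zfp831, which lay near 1 CPM in every leukemia and at 38.4 CPM in WT, was left out of the neighbours after its value was seen, the choice less favourable to this conclusion. All 18 genes were under 0.5 CPM, and a deletion or strain variant of the DNA could not be told apart from silencing. The genes were chosen for this pattern, so the count by itself is no test.

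The leukemias differed in ways not explained here. Between BN1 and MA9 the list medians of log2 fold changes were -11.33 for HoxA and 8.41 for HoxB. For BN1 and ME they were -10.98 and 10.27. MLL fusion targets other than Hox had medians of -0.95 in BN1 against MA9 and 0.04 in MA9 against ME. Early progenitor genes had -1.86 in BN1 against MA9, -1.09 in BN1 against ME and 0.53 in MA9 against ME. Neutrophil genes had 2.99 against MA9 and 2.17 against ME, and monocyte genes 1.21 and 1.28. Cell cycle genes had -0.81 and -0.71, and Myc and ribosome biogenesis genes -0.60 and -0.48. Glycolysis genes had -0.47 in BN1 against ME. The list of p53 targets and cell cycle inhibitors had 0.48 in BN1 against MA9 and 0.50 against ME. Interferon genes had 0.85 in BN1 against MA9 and -0.79 in MA9 against ME, and erythroid genes 1.12 in MA9 against ME. With genes at their bound the medians were -9.05 and -9.11 for HoxA against MA9 and ME, 9.01 for HoxB against ME, -1 for early progenitors against MA9 and 0.61 for erythroid genes.

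Many of these camera calls were lost with an estimated correlation. In BN1 against MA9 the adjusted p of camera became 0.054 for HoxB, MLL target, early progenitor and interferon genes, 0.085 for monocyte genes and 0.13 for cell cycle genes and p53 targets. In BN1 against ME it became 0.051 for HoxB, 0.066 for early progenitor, 0.15 for cell cycle and 0.39 for glycolysis genes and 0.086 for p53 targets. In MA9 against ME it became 0.2 for MLL target, 0.16 for early progenitor and 0.61 for erythroid genes.

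Hoxa9 had fitted log2 fold changes of -14.16 in BN1 against MA9 and -13.82 against ME, resting on 1 count in BN1. Meis1 had -10.00 and -8.15. Cd34 had -6.27 in BN1 against MA9 and 3.77 in MA9 against ME.

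Regrouping the libraries of a comparison gives 10 splits for 3 against 3, too few for a share under 0.05. Each split was fitted with only the libraries of the groups compared, so the counts differ from those of the model over all 12 libraries. The real grouping gave 11941, 12035, 11778, 10145, 9556 and 5914 called genes in BN1, MA9 and ME against WT, BN1 against MA9, BN1 against ME and MA9 against ME, and 1 split of 10 in each reached as many. The highest other split gave 0 in edgeR after adjustment and 37, 11, 11, 166, 152 and 272 genes at an unadjusted p under 0.05. Called lists numbered 18, 19, 17, 11, 9 and 6, with 19, 19, 19, 10, 9 and 4 in the highest other split, and 3, 2, 8, 1, 2 and 1 splits reached as many. For BN1 against both MLL fusions, MA9 and ME were joined into a single group of 6 libraries, which adds their difference to the spread and gave fewer calls than the 10579 of the model over all libraries. In that fit 8168 genes were called and 2255 in the highest other of 84 splits, 1 split reaching as many. The 9 lists called there were reached by 18 of 84 splits (highest other 11). Libraries clustered by group, no label states independence, and other splits keep some group differences. Splits thus cannot decide on chance for genes or lists.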

How the results depend on the processing

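The 3 libraries per group and unstated origin of replicates limit every p-value, and the cause of each change below was not tested. In the order BN1, MA9 and ME against WT, BN1 against MA9, BN1 against ME, MA9 against ME and BN1 against both, a 2-fold minimum left 5786, 5929, 5795, 3649, 3391, 1907 and 3470 genes. Over other tools, scalings and filters the counts ran from 11387 to 13684, 11508 to 13535, 11386 to 13478, 9911 to 10872, 9507 to 10372, 5849 to 6406 and 10099 to 11118. Which direction held more calls depended on the scaling in all comparisons but BN1 against MA9 and BN1 against ME. Of the called genes, DESeq2 shared 11528, 11624, 11506, 9779, 9380, 5681 and 10076, and limma-voom 12088, 12198, 12059, 10264, 9797, 6078 and 10473. Shared calls of at least 2-fold were 3918 for BN1 and MA9, 3973 for BN1 and ME and 4760 for MA9 and ME.

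With an estimated correlation 12 lists stayed called in MA9 against WT, 3 in BN1 against MA9, 4 in BN1 against ME, 1 in MA9 against ME and 3 in BN1 against both. The fry test called 27 lists in BN1 against WT, 26 in ME against WT, 26 in BN1 against MA9, 20 in BN1 against ME, 21 in MA9 against ME and 25 in BN1 against both.

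With a block for the replicate number the calls were 12042, 12162, 12014, 10195, 9743, 5967 and 10392, the lists 19, 19, 18, 9, 8, 1 and 8, and the shared calls 8992, 9093 and 10452. The early progenitor call was lost in BN1 against MA9 (0.063), BN1 against ME (0.057), BN1 against both (0.1) and MA9 against ME (0.089), the MLL target call (0.2) and erythroid call (0.089) in MA9 against ME; cofactors (0.044) and stroma (0.047) in BN1 against WT and stem cells (0.02) in ME against WT were gained. Same-number pairs correlated at -0.081 to 0.062 and others at -0.101 to 0.094, and 4 of 12 libraries lay closest to their own number, so the numbers do not pair libraries.

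Leaving out single libraries gave 11940 to 12061, 12091 to 12228, 11915 to 12155, 9859 to 10092, 9356 to 9670, 5523 to 5865 and 9941 to 10656 genes, and shared calls of 8865 to 8917, 8966 to 9008 and 10322 to 10365. MHC class II in BN1 against MA9 (0.051) was called with DESeq2 size factors (0.049), and MHC class II in MA9 against ME (0.16) without ME replicate 1 (0.038). Glycolysis in BN1 against MA9 (0.063) was called without MA9 replicate 2 (0.044), and cofactors in BN1 against WT (0.085) without WT replicate 2 (0.047). In BN1 against both, interferon genes (0.054) were called without BN1 replicate 1 (0.046), BN1 replicate 3 (0.042) or ME replicate 1 (0.044), and immediate early genes (0.089) without BN1 replicate 1 (0.046). Chosen after seeing the data, fits without structural RNA-like genes gave 12156, 12283, 12156, 10385, 9920, 6222 and 10595, and fits without X and Y genes 11804, 11936, 11800, 10067, 9627, 6043 and 10262. Over single genes followed through the alternatives, 33755 values stayed the same, 201 calls were gained, 593 were lost and 0 reversed.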

Other observations

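The azurophil granule gene Elane and the secondary granule gene lactoferrin (Ltf) differed between the leukemias. Elane stood at 5190.4 ± 170 CPM in BN1, 3676 ± 104 in MA9 and 4307 ± 51.4 in ME, while Ltf stood at 1128 ± 14.1, 6.95 ± 0.857 and 0.635 ± 0.158 CPM. In BN1 the surface receptor Kit rose against WT (1.28 ± 0.06) and the antigen Cd34 fell (-5.57 ± 0.17), whereas in MA9 Kit (0.55 ± 0.06) and Cd34 (0.70 ± 0.10) both rose.

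The male germ line gene Dmrtb1 was active in BN1 at 356 ± 8.69 CPM and in ME at 172 ± 4.46, and low in MA9 at 3.17 ± 0.155 and WT at 0.0913 ± 0.0672.

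Bmi1 rose in each leukemia, by 0.83 ± 0.07 in BN1, 0.55 ± 0.08 in MA9 and 0.66 ± 0.08 in ME. It was also higher in BN1 than in MA9 (0.27 ± 0.07) and ME (0.16 ± 0.07).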
